A study of Moricandia suffruticosa and Brassica napus with 23 samples.

How the data were processed

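The 9 leaf libraries analysed were of Brassica napus: 3 control, 3 drought (water withheld for 3 days) and 3 heat (40 °C for 3 h), from 35-day plants. The column names of the table fit the sample titles of both species apart from the species prefix. They were assigned to Brassica napus because the table holds Brassica napus gene models and its name carries the code of those samples. The series has 23 samples, and the 14 of Moricandia suffruticosa were not analysed here.

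Reads were aligned with HISAT2 (version not given in the sources used here), per the submitters' processing notes. The genome build, the annotation version and the counting tool are not given in the sources used here. The unit of the values is not stated either. From the values, the table deposited by the authors holds FPKM: each value times the coding length, taken as 3 times the protein length plus 1, is a whole multiple of 1 step per library for at least 99.4% of genes with a value above 0, within a tolerance of 0.01. Whether reads or fragments were counted is not stated, so RPKM would describe the values equally well, and "reads" below stands for either. Whole reads came out in all 9 libraries for 88024 genes, 99.6% of those with a coding length. Assigned reads ranged from 12173804 to 12934922 per library, so that 1 read on 1 kb was 0.0773 to 0.0821 FPKM and a gene of 1 FPKM and 1 kb rests on about 12 to 13 reads.

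The table lists 101040 genes, 88392 of them with a best Arabidopsis match at 21772 loci. Values were used as log2(FPKM + 1) without further scaling. Genes with at least 1 FPKM in at least 3 libraries were tested, 44260 in all. limma 3.58.1 in R 4.3.3 fitted 1 mean per group over the 9 libraries, with a mean-variance trend and robust moderation, and gave drought against control, heat against control and heat against drought. P-values were adjusted by the method of Benjamini and Hochberg within each comparison, and a gene was called at an adjusted p under 0.05 and a log2 change of at least 1 in size. These choices, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where said otherwise.

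Of the 28 gene lists, 26 hold 380 Arabidopsis loci and were matched by locus, while cytosolic ribosomal proteins and core histones were matched by protein description; 2 tested genes stand in more than 1 list. Each list was tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, with adjustment over the lists of a comparison. Named genes are, for each treatment, the 12 largest rises and the 8 largest falls among called genes with a known description, a mean of at least 10 FPKM in the higher group and all treated libraries beyond all controls, 1 gene per locus, and the 3 members of each list with the smallest adjusted p among those with a mean of at least 1 FPKM. InterPro entries were used for enrichment because the table held no GO or KEGG columns, a choice made after the table was seen. Entries with 10 to 500 tested genes (826 entries, 37259 genes as background) were tested with a one-sided hypergeometric test. The overlap of drought and heat calls was set beside independent lists and beside 20 simulations of unchanged groups against the same controls.

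Alternatives were TMM factors computed on the values (trims of 30% and 5%), quantile normalization, limma without trend and robust moderation, a pseudocount of 0.1, no filter, a filter of 5 FPKM, the replicate number as a block, only the groups compared, copies of 1 locus summed, no fold threshold, lists matched by description, and leaving out each library in turn. limma's voom on the recovered reads was added after the data were seen. In data simulated from the real control means, 200 genes were changed, all with at least 5 FPKM in all 9 libraries, so recovery of lower genes was not measured. The variance was a fixed multiple of read sampling, without a part that grows with depth. Recovered were all genes changed 3-fold or 4-fold upward, and 32.4% (drought) and 29.4% (heat) of those changed 2-fold. Downward, the shares were 24.2% and 21.2% at 0.5-fold, 97.0% and 93.9% at 0.333-fold, and 100% and 97.0% at 0.25-fold. Of unchanged genes, 1 of 39894 and 2 of 39902 were called. A true 2-fold or 0.5-fold change lies just inside the threshold on the log2(FPKM + 1) scale, so its low recovery was set by the threshold. Tables and figures were made with the R package data.table (1.17.8), Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9.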

Results

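Messenger RNA was measured in leaves of Brassica napus (oilseed rape) under normal watering, under drought and under heat. The plants had grown in soil for 35 days at 25 °C and 60% humidity with 16 h of light. Drought plants had water withheld for 3 days, and heat plants were kept at 40 °C for 3 h. Each of the 3 groups had 3 libraries of polyadenylated RNA, so n = 3 stands behind every mean and SD below. The series also holds 14 samples of Moricandia suffruticosa, a wild crucifer, and the comparison of the species named in the series title was not analysed here. The table of values listed 101040 genes, of which 31696 stood at 0 in all 9 libraries and 44260 were tested. Reads assigned to genes ranged from 12173804 to 12934922 per library, and 1 read on a gene of 1 kb coding length was worth 0.0773 to 0.0821 FPKM (fragments per kilobase of coding length, scaled to the fragments assigned).

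Libraries of one group were alike across genes, with correlations of log2(FPKM + 1) from 0.983 to 0.986 within groups. Those correlations were 0.891 to 0.893 between control and drought, 0.818 to 0.820 between control and heat, and 0.805 to 0.809 between drought and heat. The first principal component held 61.2% of the variance and the second 29.9%. Among genes of 10 to 1000 reads in a replicate pair, a constant part of the variance was 1.42 to 1.62 times that of read sampling. The part that grows with depth was on top of it, a coefficient of variation of 0.883% to 2.82%. It was 5.65% and 5.66% in the pairs that held drought replicate 3. For genes of at least 10000 reads, the mean squared difference within pairs was 3.22 to 44.0 times that of read sampling. The labels do not say whether the libraries of a group came from separate plants, so the p-values measure the spread between these libraries, which may be technical. Oilseed rape carries several copies of most Arabidopsis genes, and how reads were split between near-identical copies is not given, so the value of a single copy is uncertain where copies are close. Gene symbols are those of the best Arabidopsis match in the table, except where copies are summed. There the symbols of the gene lists are used, so that HSP17.6C is the locus AT1G53540 and HSP22 the locus of ATHSP22.0.

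Drought against control asked how leaves respond to withheld water. Heat-shock genes gave the largest rises. HSP18.2 (BnaA03g09300D), a small heat-shock protein that holds unfolded proteins, went from 1.84 ± 0.0968 to 1484 ± 39.0 FPKM, 806-fold in the ratio of means. The cytosolic chaperone Hsp70b (BnaA06g10730D) went from 2.25 ± 0.124 to 832.7 ± 29.4 FPKM, and RAB18 (BnaC09g08130D), a dehydrin of water-stressed tissue, from 1.02 ± 0.378 to 298 ± 15.9 FPKM. The largest fall was in CYP79A2 (BnaA10g25130D), a cytochrome P450 that makes phenylacetaldoxime, from 132.9 ± 7.20 to 0.714 ± 0.0927 FPKM.

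In all, 2265 genes were higher and 3039 lower in drought, of 44260 tested. With TMM factors (a trimmed mean of the log ratios between libraries) these were 2634 and 2703, and with quantile normalization 2454 and 2709. A pseudocount of 0.1 gave 3167 and 4813, and voom on the recovered reads 3124 and 4884. A gene counted as changed at an adjusted p under 0.05 and a fold of at least 2 on the log2(FPKM + 1) scale, which understates the change of low genes. The groups did not overlap in 54.7% of genes, against 10% expected by chance for 3 libraries against 3. The median log2 change over all genes was -0.06.

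Among the 12 largest rises, 8 were small heat-shock proteins or other members of that fold. They included AT1G53540 (BnaA10g12710D, log2 change 9.02 ± 0.11 SE), HSP17.6II (BnaC09g44630D, 7.92 ± 0.17), ATHSP22.0 (BnaC03g28860D, 7.91 ± 0.10), the plastid HSP21 (BnaC01g20320D, 7.12 ± 0.08) and the mitochondrial HSP23.6-MITO (BnaC01g17140D, 6.66 ± 0.05). The chloroplast protease gene FTSH6 (BnaA10g18880D) rose by 7.45 ± 0.20, and GolS1 (BnaA04g26930D), which makes galactinol for raffinose sugars, by 6.75 ± 0.12. Adjusted p-values of the 12 genes lay between 1.37e-16 and 2.58e-10 in limma. After CYP79A2, the largest falls were in AAS (BnaC09g10380D, -5.61 ± 0.17), an aromatic aldehyde synthase, CYP71B20 (BnaA10g24620D, -5.45 ± 0.15) and CYP71A13 (BnaA03g14120D, -5.27 ± 0.11), an enzyme of camalexin synthesis. Of 5 copies of AAS tested, 3 were lower. The identity of BnaA10g24620D to its Arabidopsis match was only 37.9%, so that symbol is uncertain. JAZ8 (BnaA08g17540D), a repressor of jasmonate signalling that jasmonate itself induces, fell by 5.06 ± 0.21 from 49.5 ± 4.19 FPKM.

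Of the 28 gene lists fixed before the data were examined, 16 passed limma's camera test of a list against all other genes in drought, 9 with a median above 0 and 7 below. Below, a list that did not pass is one that camera did not call against the other genes, which says nothing of whether its members changed. Fry, which tests the members of a list by themselves for a shared direction, called 22 lists in drought, among them the 16 of camera in the same direction. Counts adjusted over the list alone were equal to those over all genes tested, for every list and comparison. Small heat-shock proteins had 39 of 43 members higher and 0 lower, with a median log2 change of 5.51. Large chaperones had 40 of 99 higher and 4 lower, and heat-shock factors 27 of 50 higher and 0 lower. HSFA2 (BnaC03g26940D), a factor that prolongs the heat-shock response, went from 11.1 ± 1.03 to 296 ± 9.14 FPKM, and MBF1C (BnaA07g05600D) from 41.3 ± 1.13 to 368 ± 28.3 FPKM. HSFA7A (BnaA03g41540D) was listed at 0 in the 3 control libraries and reached 25.5 ± 0.721 FPKM. Protein folding genes of the endoplasmic reticulum had 25 of 55 members higher and 2 lower, among them ATERDJ3A (BnaCnng24180D), by a log2 change of 3.38 ± 0.07 SE.

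The list of late embryogenesis abundant proteins and drought markers had 29 of 50 members higher and 3 lower, with a median of 1.36. The dehydrin ERD10 (BnaC05g15780D) rose by a log2 change of 2.82 ± 0.04 SE to 2414 ± 64.7 FPKM and RD22 (BnaA06g39340D) from 309.6 ± 6.06 to 917 ± 14.6 FPKM. Only 2 of 5 copies of RD22 tested were called higher. Clade A protein phosphatases 2C, which brake abscisic acid signalling and are induced by it, had 10 of 25 higher and 0 lower. Among them was PP2CA (BnaC05g41830D), from 64.5 ± 2.74 to 222 ± 3.58 FPKM, with 2 of 4 copies tested called higher. Raffinose family synthesis had 7 of 15 higher and 0 lower. Chlorophyll breakdown and senescence had 18 of 36 higher and 0 lower, among them NAP (BnaC06g30680D), a factor of leaf ageing, from 2.16 ± 0.211 to 20.4 ± 1.82 FPKM. Antioxidant enzymes passed the test with a median of 0.07, 12 of 67 members higher and 1 lower; CAT2 (BnaC03g65530D), a catalase of photorespiration, stood at 885 ± 17.3 and 2149 ± 93.0 FPKM, a call that ended with the copies of its locus summed (log2 change 0.59).

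Photosynthesis, jasmonate and glucosinolate genes went the other way. Light harvesting and photosystem subunits had 40 of 151 members lower and 2 higher, with a median of -0.65. CAB1 (BnaA07g07560D), a chlorophyll a/b binding protein, went from 848 ± 8.60 to 223 ± 8.54 FPKM, and 9 of 9 copies tested were lower. Carbon fixation had 8 of 42 lower and 0 higher, and chlorophyll synthesis 6 of 42 lower and 1 higher. That one riser was HEMA1 (BnaA03g59660D), from 3.57 ± 0.243 to 159.6 ± 11.5 FPKM, 1 of 5 copies tested and not called with the copies summed (0.67), while PORB (BnaC01g19630D) fell from 45.7 ± 1.65 to 9.01 ± 0.997 FPKM. Jasmonate synthesis and response had 49 of 60 members lower and 0 higher, with a median of -2.45. AOS (BnaA02g23180D), an enzyme of jasmonate synthesis, went from 164 ± 1.95 to 24.3 ± 0.0482 FPKM, and the repressor JAZ6 (BnaC06g33640D) from 323 ± 9.45 to 29.5 ± 1.41 FPKM. Glucosinolate synthesis had 36 of 57 lower and 1 higher, among them the sulfotransferase SOT16 (BnaAnng27200D) from 169 ± 3.15 FPKM by a log2 change of -2.79 ± 0.05 SE.

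Aquaporins had 15 of 54 members lower and 5 higher, and cuticular wax synthesis 16 of 50 lower and 3 higher. The vacuolar aquaporin TIP2 (BnaA02g28130D) fell from 1060.3 ± 10.8 to 162 ± 4.82 FPKM, and the wax gene CER4 (BnaC01g04460D) from 103 ± 1.73 to 12.2 ± 1.19 FPKM. The camera call of these lists was lost when the correlation was estimated, with an adjusted p = 0.306 for aquaporins and an adjusted p = 0.079 for wax. The other 14 calls in drought held with an estimated correlation. With members taken by protein description, the calls for clade A phosphatases (median 0.34) and carbon fixation (-0.42) ended, and with the copies of a locus summed those for antioxidant enzymes (0.06) and aquaporins (-0.49) did; the antioxidant call also ended with quantile normalization (0.09).

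The lists that did not pass camera in drought were abscisic acid synthesis and breakdown (5 of 33 higher, 2 lower), abscisic acid receptors (3 of 32 higher, 3 lower), proline metabolism (3 of 17 higher, 3 lower), salicylate and pathogen response (0 of 36 higher, 2 lower), circadian clock (4 of 41 higher, 0 lower), cytosolic ribosomal proteins (0 of 30 either way) and core histones (1 of 34 higher, 4 lower). Without drought replicate 3 the clock (adjusted p = 0.0284) and ribosomal lists (adjusted p = 0.013) passed camera; the clock list also passed without trend and robust moderation (adjusted p = 0.0496) and with no filter (adjusted p = 0.0464), and the ribosomal list with quantile normalization (adjusted p = 0.0481). Members of these lists still changed singly. P5CS1 (BnaA05g05760D), the first enzyme of proline synthesis, rose from 19.5 ± 1.39 to 166 ± 5.53 FPKM, RCAR1 (BnaA07g38130D) from 1.44 ± 0.527 to 40.8 ± 1.58 FPKM, and NCED9 (BnaC06g38870D) fell from 50.4 ± 2.94 to 2.64 ± 0.483 FPKM. Copies called the same way were 2 of 4 tested for P5CS1 and 2 of 5 for RCAR1. Markers of other organs and cell types did not pass either, with 0 of 2 floral, 0 of 2 seed storage, 0 of 17 guard cell and 0 of 25 phloem members changed, and 1 of 3 root members, CASP1 (BnaA05g08160D), lower, a call that ended without drought replicate 1 (-0.86). The list medians for proline (0.17) and histones (-0.04) lay near 0, and for histones the test pointed up while the median lay below 0.

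InterPro protein families, tested for enrichment among the changed genes after the table had been seen, gave 37 families among the higher and 67 among the lower genes of 826 tested. The HSP20-like family had 35 of 72 members higher where 3.48 were expected, and the entry for the HSP70 conserved site 28 of 52 where 2.51 were expected. The family with the CO/COL/TOC1 conserved site, which marks JAZ proteins and related factors, had 35 of 46 members lower where 3.27 were expected, and lipoxygenases 17 of 24 where 1.71 were expected. With the copies of 1 Arabidopsis locus counted as 1, 8 and 19 families passed, and lipoxygenases were not among them (adjusted p = 0.0719).

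**Figure D1:**
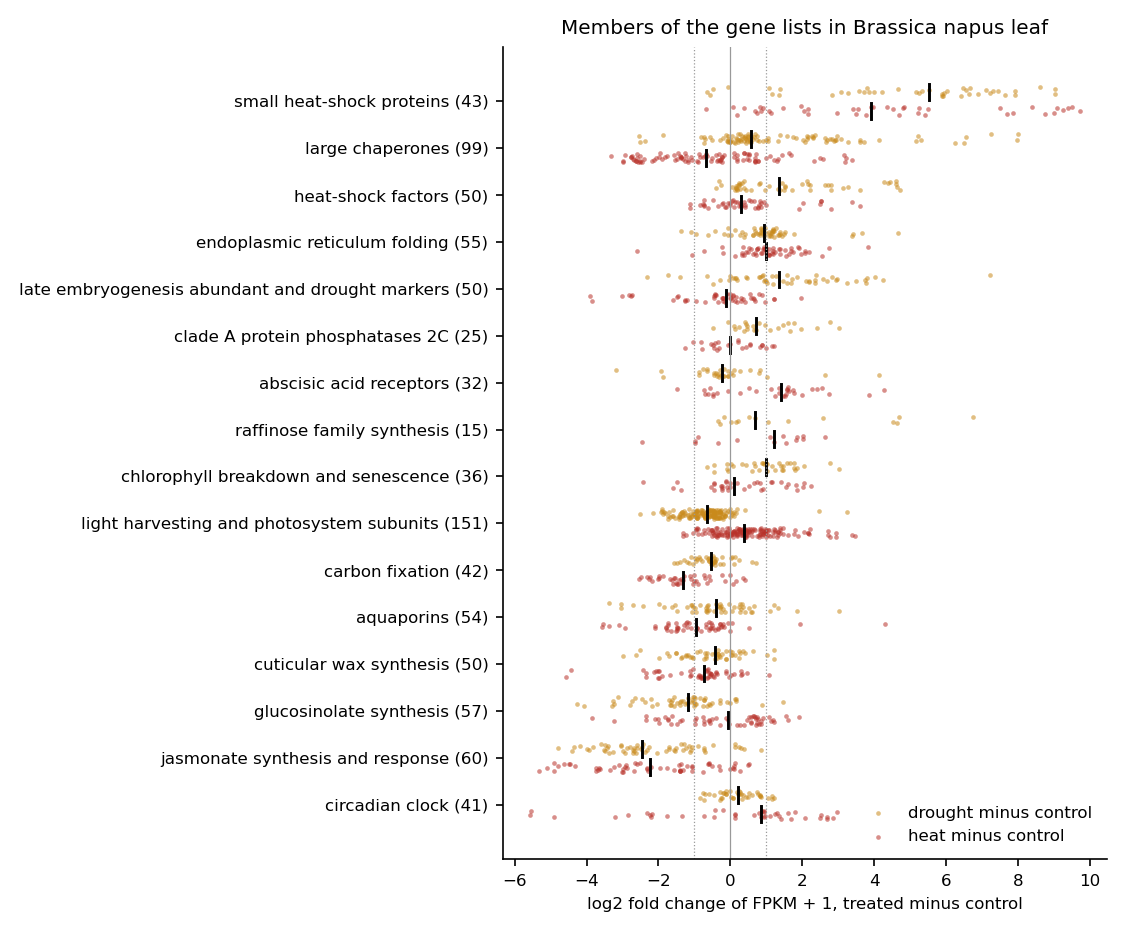
Each point is 1 tested gene of 16 of the fixed lists, with its log2 fold change of FPKM + 1 against control on the x axis, drought in ochre above heat in red; numbers in brackets count the members and black bars are medians. Small heat-shock proteins lay to the right in both treatments (medians 5.51 and 3.91), large chaperones parted (0.58 and -0.69) and jasmonate genes lay to the left in both (-2.45 and -2.24).

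Heat against control asked how leaves respond to 3 h at 40 °C. Small heat-shock proteins again gave the largest rises, above their level in drought for several genes. AT1G53540 (BnaA02g06890D) went from 5.53 ± 0.915 to 5434 ± 225 FPKM, 983-fold in the ratio of means, and HSP21 (BnaC01g20320D) from 0.774 ± 0.238 to 954 ± 50.3 FPKM. GRP7 (BnaUnng05060D), an RNA-binding protein whose Arabidopsis counterpart peaks in the evening, went from 1.12 ± 0.180 to 521 ± 33.9 FPKM. LHY (BnaAnng17890D), a morning factor of the clock, fell from 97.9 ± 2.77 to 1.12 ± 0.351 FPKM, and TT4 (BnaC02g05070D), the chalcone synthase that opens flavonoid synthesis, from 303.6 ± 9.52 to 1.36 ± 0.513 FPKM.

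In all, 6366 genes were higher and 4970 lower in heat, of 44260 tested. The groups did not overlap in 71.4% of genes, against 10% by chance. With TMM factors the median log2 change over all genes moved from 0.16 by -0.15, so that 45.0% of the changed genes were higher in place of 56.2%.

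The other large rises were in ATHSP22.0 (BnaA03g24280D, log2 change 9.39 ± 0.06 SE), HSP18.2 (BnaA03g09300D, to 514 ± 3.32 FPKM), the DnaJ-type chaperones AT1G71000 (BnaC06g32130D, 7.28 ± 0.10), AT3G13310 (BnaC05g40060D, 6.46 ± 0.19) and AT1G56300 (BnaAnng20610D, 5.99 ± 0.23), the glycosyl hydrolase AT3G62710 (BnaC04g55020D, from 0.217 to 153.8 ± 3.74 FPKM), PIFI (BnaA05g23700D, 6.16 ± 0.24) and CCL (BnaC09g01160D, 6.10 ± 0.10). DAR6 (BnaC09g07940D) rose by 7.02 ± 0.14, while of its 4 copies tested 1 was higher and 2 were lower. After TT4, the largest falls included CYP79A2 (BnaA10g25130D, -6.72 ± 0.10), the methyltransferases AT3G44870 (BnaC08g34950D, -6.69 ± 0.12) and BSMT1 (BnaA03g31730D, -6.01 ± 0.10), JAZ7 (BnaA03g15910D, -5.82 ± 0.16) and XTH6 (BnaCnng13310D, -5.49 ± 0.10), a cell wall enzyme. The largest adjusted p among the 20 genes taken for their size of change was 1.54e-09 in limma.

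Of the 28 lists, 11 passed camera in heat, 5 with a median above 0 and 6 below. Fry called 26, the 11 of camera in the same direction and 15 of the 17 that did not pass camera. Small heat-shock proteins had 34 of 43 members higher and 0 lower, with a median of 3.91. Endoplasmic reticulum folding had 27 of 55 higher and 2 lower, among them the disulfide isomerase PDIL1-2 (BnaC06g38200D), which rose from 168 ± 3.88 to 718 ± 5.31 FPKM. Large chaperones had 43 of 99 lower and 14 higher, with a median of -0.69, and that call was lost with an adjusted p = 0.0866 with an estimated correlation. Among the members that rose was the peptidyl-prolyl isomerase AT5G48570 (BnaA06g30120D), from 25.0 ± 2.07 to 231 ± 5.01 FPKM. The call for large chaperones also ended with the copies of a locus summed, where the median was 0.12, and turned with members taken by protein description, where it was 0.52. Heat-shock factors did not pass, with 8 of 50 higher and 2 lower. HSFA3 (BnaCnng02620D) rose from 0.498 ± 0.305 to 16.9 ± 0.413 FPKM. HSFA2, chosen after its values were seen, did not rise in heat. Summed over its copies, it stood at 16.5 ± 2.03 FPKM in control and 8.16 ± 1.12 FPKM in heat.

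Abscisic acid receptors had 20 of 32 members higher and 1 lower, among them PYL6 (BnaC03g22610D) from 0.937 ± 0.309 to 36.0 ± 4.18 FPKM (adjusted p = 0.0866 for the list with an estimated correlation). The late embryogenesis abundant and drought marker list did not pass in heat, with 3 of 50 higher and 12 lower. RD26 (BnaA01g16400D), a factor induced by drought and abscisic acid, fell from 59.7 ± 3.55 to 3.07 ± 0.602 FPKM. Raffinose family synthesis had 9 of 15 members higher and 1 lower and did not pass.

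Photosynthesis genes split in heat. Light harvesting and photosystem subunits had 34 of 151 members higher and 4 lower (adjusted p = 0.426 for the list with an estimated correlation). LHB1B1 (BnaC04g10780D) went from 523.6 ± 12.9 to 3456 ± 47.5 FPKM, and CAB1 (BnaAnng22920D) from 963 ± 9.07 to 4281 ± 86.6 FPKM, though only 2 of 9 copies of CAB1 were higher. Carbon fixation had 28 of 42 members lower and 0 higher, with a median of -1.32. RCA (BnaC04g46560D), which activates Rubisco, went from 9910 ± 127 to 2507 ± 70.2 FPKM and GAPB (BnaA08g04610D) from 1652 ± 17.1 to 453 ± 5.58 FPKM. Chlorophyll synthesis did not pass, with 5 of 42 higher and 3 lower; the 5 risers were the 5 copies of PORB, among them BnaC01g19630D at 462 ± 14.9 FPKM. Its median (-0.10) and its mean (0.28) differed in sign, and the test pointed down. CAT3 (BnaC07g15280D), a catalase of the evening in Arabidopsis, rose from 375 ± 1.99 to 3743 ± 9.25 FPKM, while the antioxidant list did not pass (15 of 67 higher, 8 lower, with the test pointing down and the median at 0.09).

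Jasmonate synthesis and response had 45 of 60 members lower and 0 higher, with a median of -2.24. AOC2 (BnaA06g33410D) went from 153 ± 2.39 FPKM by a log2 change of -4.90 ± 0.07 SE and OPR3 (BnaA03g38210D) from 265 ± 5.64 to 12.3 ± 0.968 FPKM, both enzymes of jasmonate synthesis. Aquaporins had 26 of 54 lower and 2 higher, among them the plasma membrane aquaporin PIP2A (BnaA09g33720D) from 1308 ± 0.796 to 110.1 ± 7.53 FPKM. Cuticular wax synthesis had 18 of 50 lower and 1 higher, led by WSD1 (BnaC06g12160D), a wax ester synthase, to 2.87 ± 0.341 FPKM, a log2 change of -4.57 ± 0.07 SE. Salicylate and pathogen response had 9 of 36 lower and 4 higher (adjusted p = 0.0866 with an estimated correlation), and the glucanase BGL2 (BnaA04g02490D) went from 252 ± 12.5 to 11.9 ± 0.647 FPKM. Cytosolic ribosomal proteins had 2 of 30 higher and 0 lower (median 0.46, adjusted p = 0.453 with an estimated correlation), and that call also ended with TMM factors (median 0.28), without trend and robust moderation (adjusted p = 0.0672) and without control replicate 3 (adjusted p = 0.0558). Summing copies ended the calls for abscisic acid receptors (1.31), salicylate response (-0.63) and ribosomal proteins (0.40). The 6 other calls in heat held with an estimated correlation, small heat-shock proteins at an adjusted p = 0.0499.

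The circadian clock list had 15 of 41 members higher and 11 lower in heat and did not pass as matched by locus, while with members taken by protein description it passed (median 1.36, adjusted p = 0.000695 in camera). By locus the median was 0.85, while fry pointed down (adjusted p = 0.00259) and gave an adjusted p = 1.85e-11 for members changing either way. LHY (BnaA10g00780D) fell from 174 ± 3.09 to 2.77 ± 0.512 FPKM, and 3 of 3 copies tested were lower. The remaining lists did not pass camera: abscisic acid synthesis and breakdown (3 of 33 higher, 10 lower; passed with a filter of 5 FPKM at a median of -1.06), clade A protein phosphatases 2C (3 of 25 higher, 2 lower), proline metabolism (3 of 17 higher, 4 lower), chlorophyll breakdown and senescence (10 of 36 higher, 4 lower; called downward by description at a median of -0.22), glucosinolate synthesis (7 of 57 higher, 15 lower), core histones (7 of 34 higher, 4 lower), floral (0 of 2 higher, 1 lower), seed storage (2 of 2 higher), root (0 of 3 higher, 1 lower), guard cell (0 of 17 higher, 1 lower) and phloem markers (1 of 25 higher, 4 lower). For clade A phosphatases the test pointed down with a median of 0.00. The seed storage members were copies of OLEO1, an oil body protein, and the higher of them (BnaC08g11970D) stood at 1.26 ± 0.220 and 15.2 ± 1.75 FPKM.

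Among InterPro families, 25 were enriched among the higher and 86 among the lower genes in heat. The HSP20-like family had 37 of 72 members higher where 10.1 were expected, and pentatricopeptide repeat proteins, which process RNA in organelles, 68 of 203 where 28.4 were expected. Aquaporin-like proteins had 32 of 73 members lower where 8.29 were expected. With copies of 1 locus counted as 1, the number of families was 2 and 22, and the HSP20-like family was not among them (adjusted p = 0.371).

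**Figure D2:**
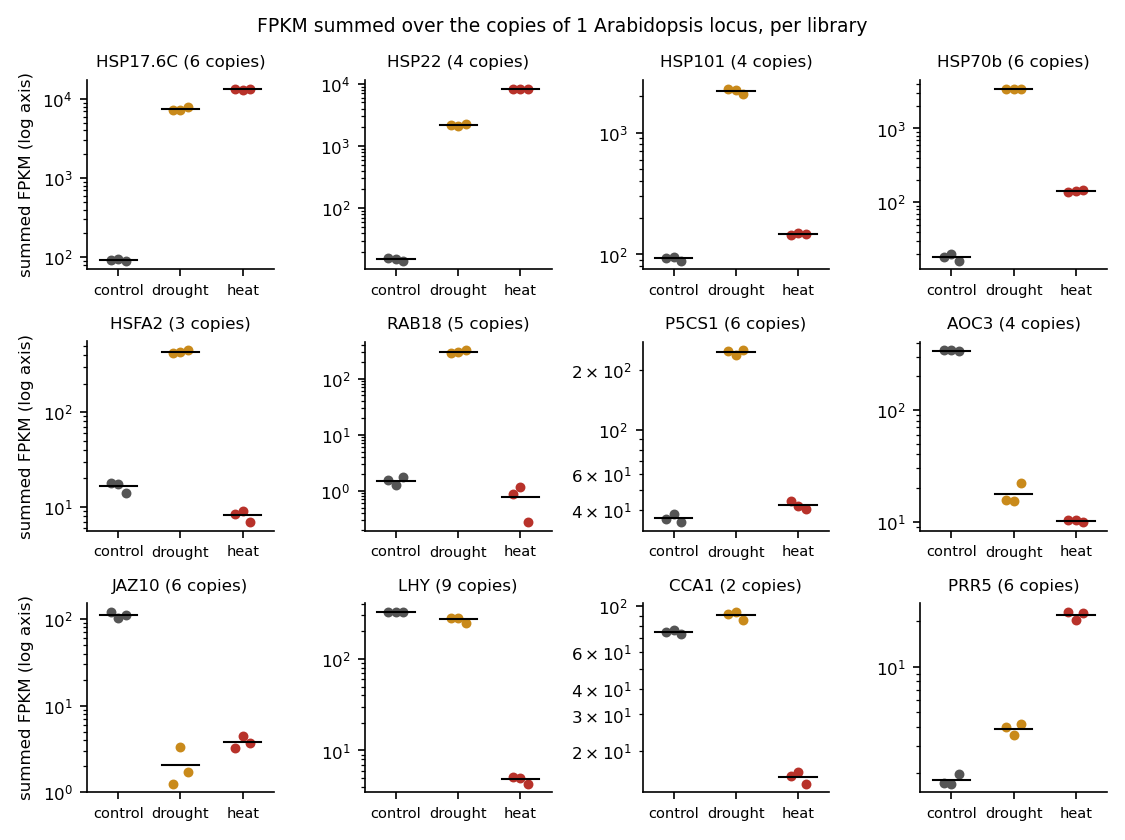
Points are the FPKM of single libraries summed over the copies of 1 Arabidopsis locus, on log axes, with bars at the means of 3 libraries per group; the 12 loci were chosen after their values were seen. HSP101, HSP70b, HSFA2, RAB18 and P5CS1 stood highest in drought, HSP17.6C and HSP22 in heat, AOC3 and JAZ10 in control, and LHY and CCA1 were lowest in heat.

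The contrast of heat and drought tested whether the treatments differed from each other; its example genes were chosen after their values were seen. Large chaperones, heat-shock factors and drought markers were higher in drought as lists. Hsp70b (BnaA06g10730D) stood at 832.7 FPKM in drought and 32.6 ± 0.264 FPKM in heat, a log2 difference of -4.63, HSFA2 (BnaC03g26940D) was lower in heat by a log2 difference of -5.37, and RAB18 (BnaC09g08130D) by -7.65. ATHSP22.0 (BnaA09g23670D) differed the other way, at 216 ± 14.6 FPKM in drought and 1799 ± 14.6 FPKM in heat. LHB1B1 (BnaC04g10780D) stood at 174 ± 8.05 FPKM in drought and 3456 ± 47.5 FPKM in heat. Adjusted p-values of these 5 genes were between 1.80e-14 and 8.88e-11 in limma.

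Summed over gene copies, HSP101, the chaperone that dissolves protein aggregates, stood at 92.9 ± 3.68 FPKM in control, 2190.3 ± 121 in drought and 148 ± 1.83 in heat. HSP17.6C stood at 92.6 ± 2.68, 7524 ± 397 and 13296 ± 357 FPKM. Of 44260 genes, 7756 were higher and 4891 lower in heat than in drought. With TMM factors the median over all genes moved by -0.22 and 45.6% of the changed genes were higher in heat in place of 61.3%. Large chaperones had 69 of 99 members lower and 4 higher in heat than in drought, heat-shock factors 19 of 50 lower and 2 higher, the drought marker list 37 of 50 lower and 1 higher, clade A phosphatases 9 of 25 lower and 0 higher, and chlorophyll breakdown 13 of 36 lower and 4 higher. Carbon fixation had 16 of 42 lower and 4 higher, and abscisic acid synthesis and breakdown 13 of 33 lower and 3 higher. Glucosinolate synthesis had 32 of 57 members higher in heat than in drought and 3 lower. These 8 calls held with an estimated correlation, at adjusted p-values of 0.00836 to 0.044. The call for abscisic acid synthesis ended with copies summed (-0.21) and by description (-1.12), for clade A phosphatases by description (-0.46) and for chlorophyll breakdown with a filter of 5 FPKM (-0.77).

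Photosystem subunits had 77 of 151 members higher in heat than in drought and 3 lower (adjusted p = 0.101 with an estimated correlation), and small heat-shock proteins 21 of 43 lower and 13 higher (adjusted p = 0.329 with an estimated correlation). The calls for abscisic acid receptors, chlorophyll synthesis, aquaporins and salicylate response were lost at an adjusted p = 0.0896 with an estimated correlation, those for raffinose at an adjusted p = 0.101, for proline and wax at an adjusted p = 0.248 and for ribosomal proteins at an adjusted p = 0.406. Summing copies also ended each of these calls but that for aquaporins. TMM factors ended those for raffinose (-0.77), proline (-0.42) and chlorophyll synthesis (0.07), and quantile normalization those for raffinose, proline and salicylate response. The proline call also ended without heat replicate 2 and without heat replicate 3. Camera did not call jasmonate genes between the treatments, with 13 of 60 higher and 8 lower in heat, while fry gave an adjusted p = 0.0013. Nor did camera call endoplasmic reticulum folding (12 of 55 higher, 9 lower), antioxidant enzymes (12 of 67 higher, 13 lower), the clock list (16 of 41 higher, 14 lower) or core histones (5 of 34 higher, 1 lower). Fry called each of these (adjusted p = 0.026, 0.000312, 2.39e-05 and 0.0018), and 8 of the 10 lists that camera did not call. The clock list passed with members taken by description (median 1.27) and the antioxidant list with TMM factors (-0.39). Among InterPro families, 34 were enriched among the genes higher in heat than in drought and 58 among the lower ones. With copies of 1 locus counted as 1, these numbers were 0 and 3. Without heat replicate 1 they were 22 and 56.

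Drought and heat changed some of the same genes. Higher in both treatments were 579 genes, where independent lists would share 325.8, and lower in both were 1439, where independent lists would share 341. Higher in drought and lower in heat were 229 genes against 254 for independent lists, and lower in drought and higher in heat 221 against 437. In the same order, a pseudocount of 0.1 gave overlaps of 1191, 1900, 431 and 657, and voom gave 1113, 1981, 438 and 701. The values for independent lists were not recomputed for these. The same control libraries served both comparisons, and in 20 simulations of unchanged groups against shared controls the number of genes changed alike was 0 on average. The simulation leaves out real effects and the independent lists leave out the shared controls, so neither excess is a measure of a shared effect, and 3 controls cannot be split into parts of 2. Across genes, the log2 changes of the treatments correlated at 0.32 where unchanged groups gave 0.50, and their covariance was 0.256 against 0.0126 in the simulation, a difference of 0.243. The simulated 0.50 arises from shared controls without any effect, so it sets no level for the correlation of real changes. Of the 2836 genes changed in drought alone, 1817 also differed between heat and drought, and of the 8868 changed in heat alone, 6661 did.

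**Figure D3:**
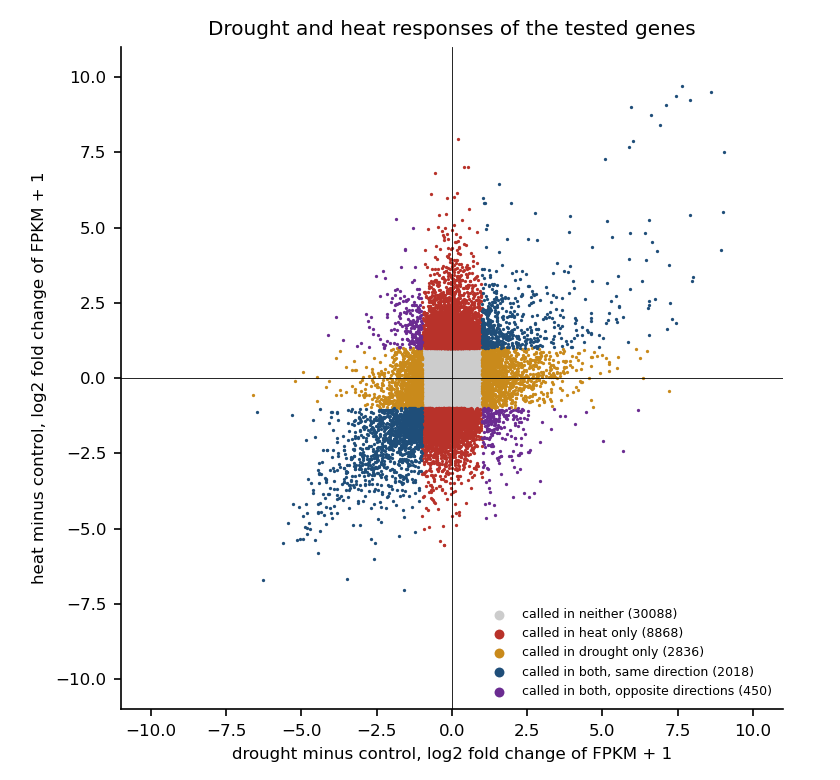
Each point is 1 of 44260 tested genes, with its log2 fold change of FPKM + 1 in drought on the x axis and in heat on the y axis. Colours show genes changed in drought alone (2836), in heat alone (8868), in both alike (2018), in both with opposite signs (450) or in neither. Small heat-shock proteins lie at the upper right, and genes lower in both form the arm at the lower left.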

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

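Depth limits genes of low value, since 1 read on 1 kb is 0.0773 to 0.0821 FPKM, and the log2(FPKM + 1) scale shrinks their changes. Voom was chosen after the data were seen; the other alternatives were planned. All counts stayed within 1.5 times under TMM factors, quantile normalization, limma without trend and robust moderation and only the groups compared. TMM factors turned no call, and kept 4966 of 5304 drought calls, 9840 of 11336 heat calls and 10379 of 12647 calls between the treatments. Genes higher and lower were then 2634 and 2703 in drought, 4870 and 5951 in heat, and 5488 and 6534 in heat against drought.

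Summing copies left 17662 loci or genes to test, so counts fell by construction: 905 higher and 1252 lower in drought, 2646 and 1788 in heat, 3204 and 1768 in heat against drought. The overlaps were then 250 higher in both, 537 lower in both, 83 higher in drought and lower in heat and 94 the reverse, and 3 lists were past the threshold upward in heat. With no fold threshold the counts rose by construction to 8654 and 11724 in drought, 17755 and 12196 in heat, 18993 and 11811 in heat against drought, and overlaps of 4215, 5454, 2131 and 3394. A pseudocount of 0.1 gave 4813 genes lower in drought and overlaps of 1191 higher in both, 431 and 657 with opposite signs. Voom gave 4884, 1113, 438 and 701 in the same order. A smaller pseudocount shrinks the changes of low genes less, and that of 0.1 kept 5272 of 5304 drought calls and turned none. How much of the rise came from low genes was not tested, nor was the cause for voom. With a filter of 5 FPKM, 26563 genes were tested and 5081 were higher in heat than in drought.

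Enriched InterPro families numbered 24 among higher and 43 among lower genes in drought and 32 among genes lower in heat than in drought with the filter of 5 FPKM (fewer genes tested). With no fold threshold they were 59 among genes higher in drought and 39 among genes higher in heat, and with no filter 39 among the latter; the cause was not tested. With the copies of a locus counted once they were 8 and 19 in drought, 2 and 22 in heat, and 0 and 3 in heat against drought.

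The large chaperone list in heat reversed to a median of 0.12 with copies summed and 0.52 with members taken by description. By description, chlorophyll breakdown in heat reversed to -0.22 and was called downward (adjusted p = 0.0448 in camera), salicylate response in heat to 0.33 and in heat against drought to 0.0968. With copies summed, ABA1 (BnaA07g12170D) in heat reversed to -0.20, BGLU18 (BnaA05g14890D) to 0.0681 and PP2CA (BnaA01g37370D) to -0.27. The cause of these reversals was not tested. Of 198 results for named genes, 27 more lost their call with copies summed and 6 with TMM factors, in the same direction.

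Leaving out each library in turn gave 2031 to 2335 genes higher and 2706 to 3102 lower in drought, 5472 to 6459 and 4683 to 5032 in heat, and 6712 to 7886 and 4620 to 4901 in heat against drought. Overlaps ranged over 578 to 609, 1174 to 1451, 225 to 232 and 209 to 240, and families enriched among genes higher in heat than in drought over 22 to 33. The expression filter was applied again each time. A gene that reached 1 FPKM only in the shortened group then left the test, so counts could fall by construction. Genes higher in heat were 5472, 5505 and 5494 without heat replicates 1, 2 and 3. Genes lower in both were 1195, 1174 and 1187 without control replicates 1, 2 and 3. These low ends point to no single library. The libraries share only replicate numbers, whose residuals correlated at -0.0184 to 0.0255 between groups, and not every library correlated best with its own number. With the number as a replicate block, 2268 genes were higher and 3041 lower in drought, 6368 and 4970 in heat and 7759 and 4894 in heat against drought, and no list or named gene changed its call.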

Other observations

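Families outside the fixed lists were enriched too, in tests on InterPro entries chosen after the table was seen. In drought, Bax inhibitor 1-related proteins, which restrain cell death, had 9 of 15 members higher where 0.725 were expected, and dehydrins 7 of 10 where 0.483 were expected. NAC proteins (no apical meristem domain) had 21 of 142 higher where 6.86 were expected. With the copies of a locus counted once, dehydrins (adjusted p = 0.0542) and NAC proteins (adjusted p = 0.0914) did not pass. Cytochrome P450 enzymes had 63 of 241 lower where 17.1 were expected, and pectinesterases 20 of 50 where 3.55 were expected. In heat, chaperonins (Cpn60 conserved site) had 13 of 22 members higher where 3.08 were expected, and protein arginine methyltransferases 14 of 26 where 3.64 were expected, and neither passed with copies counted once (adjusted p = 0.371 and 0.769). Multidrug exporters of the antimicrobial extrusion family had 34 of 82 lower where 9.32 were expected, and FAS1 proteins of the cell surface 23 of 37 (adjusted p = 6.04e-11). Proteins with EF-hands, which bind calcium, had 66 of 208 members lower in heat than in drought where 22.7 were expected.

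The tests of exchanged labels, scaling, gene copies, heat acting on the clock, an unusual control library and other splits were chosen after the results were seen; the morning, evening, touch and wound lists were written before their own values were seen.

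Heat-shock genes were higher in drought than in heat libraries for large chaperones and heat-shock factors. Exchanged labels would put drought markers higher in the heat libraries, and their median heat minus drought was -1.55 with 37 of 50 lower, which argues against it. Scaling is argued against by a large chaperone median of -2.36 with TMM factors, and reads shared between copies by -2.13 with copies summed. Leaf temperature of dry plants, or the time since heat began, might also part the treatments, and neither was tested.

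Clock genes were shifted in heat libraries, with 26 of 41 members called. Sampling at another time of day could give this. In heat the evening genes had a median of 2.59 (8 of 9 higher, from 2 of 5 loci) and the morning genes -1.35 (17 of 29 lower, 2 higher), a difference of 3.94. In drought these medians were 0.06 (1 higher, 2 lower) and 0.26 (1 higher, 0 lower). Copies of CCR1 made up most of the evening list and spread from -2.17 to 1.04 in drought. The 4 medians are what the time-of-day explanation predicted. Heat acting on the clock itself may give the same 26 calls, and the labels give no time of day to tell these apart. Other heat results for genes with a daily rhythm, such as PORB and CAT3, may share this doubt.

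Jasmonate genes were highest in control libraries. Touch or wounding of control leaves might raise them. The touch and wound list had medians of -0.37 in drought (17 of 65 lower, 5 higher) and -0.80 in heat (27 lower, 4 higher). The larger of their standard errors was 0.22, taken from the spread of the 65 members as if they were independent. Those members are copies from 20 loci, so it is not an error between libraries and may be too small. By the prediction written beforehand, a median above a set bound in either comparison would count against touch, and the drought median lay above it. It lay within 0.22 of that bound, a margin that the written prediction did not hold, so this test cannot tell. An unusual control library is argued against, since the jasmonate median without each control in turn was at most -1.86. The expression filter was applied again there, so members that reached 1 FPKM only in control left the list.

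Of the 10 splits of 6 libraries into 3 and 3, only 1, the real split, gave as many calls for each comparison (5304, 11336 and 12647), and the highest other split gave 0. With 10 splits no share under 0.05 can be reached.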
